A study of Mus musculus with 4 samples.

How the data were processed

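SATB1 ChIP-seq libraries came from wild type ES cells, from cells overexpressing ALKBH1 and from wild type cells at day 5 of differentiation, with 1 library each. The cells were formaldehyde-fixed, sonicated and precipitated with an anti-SATB1 antibody, per the labels' protocols. The day 5 label spells the antibody's target Stab1 and gives the same product, and it was taken as SATB1. The labels of the wild type and overexpression libraries give no day, and the name of the day 5 comparison calls the wild type library day 0. Reads were processed with Bowtie2 2.3.1, SAMtools and SICER 1.1 on mouse build mm9, per the submitters' processing notes. The names of the deposited lists carry a mapping quality of 20, a window of 200 bp, a gap of 600 bp and an FDR of 0.01. Whether the input sample or another control entered island calling is not given in the sources used here. How PCR duplicates were handled is not given in the sources used here either.

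The authors deposited 1 island list per library, with a read count per island. SICER joins neighbouring windows with more reads than background into islands, so that island edges and numbers depend on depth. The authors also deposited 2 comparison lists, without column headers. For each merged island the authors' comparison lists give the read count in both libraries, RPM (reads per 1000000 reads of the library), the fold in both directions, and a p-value and FDR for each direction. Which library each count column holds was taken from the name of the comparison and checked on the counts. At the 5268 increased islands with the same coordinates as an overexpression island, all 5268 counts were equal to that island's. At 3325 decreased islands shared with the wild type list all 3325 were equal, and at 12 shared with the day 5 list all 12. Counts over RPM gave each library's read total, and the wild type total was the same in both lists. The authors' fold equalled, at all islands, the ratio of the counts plus 1, scaled by the read totals. The authors' deposited p-value matched, within 0.01 on the log10 scale at all 5270 and 3341 islands, a Poisson probability. That probability takes the count of the lower library as known without error. The FDR was adjusted over 18306 and 8281 merged islands, the same numbers that merging the island lists gave here.

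Island numbers, covered bases, widths and reads were computed per list with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Overlaps of at least 1 bp were counted with bedtools 2.31.1. They were set beside 100 random placements of the first list on its own chromosomes with fixed seeds, between the lowest and highest island position of any list. Chromosome length was taken as the highest island end in any list. Because no group had a second library, no test between conditions was made. Island counts have exact Poisson intervals, shares have exact Clopper-Pearson intervals, and ratios of counts have exact conditional binomial intervals, all at 95%. Intervals cover counting error at most. They and the exact p-values take reads as independent molecules, which reads without molecular identifiers need not be, so they may be too narrow. Intervals on island numbers and on ratios of island numbers take islands as independent counts. They leave out the calling threshold and the clustering of islands. For a comparison at equal depth, island reads were thinned binomially to the wild type total in 100 draws. An island was kept when it reached the lowest count of any autosomal wild type island of its width, which does not model islands that break up. Where a count was 0 the fold was computed against a floor of 3 counts per library. That floor is 0.610 RPM in wild type, 0.354 with overexpression and 0.521 at day 5. Most islands held few reads: 88.2% of the increased islands had under 30 in the overexpression library, and 97.3% of the decreased islands had under 30 in wild type.

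An exact one-sided conditional binomial test on both counts, with Benjamini-Hochberg adjustment over all merged islands, was added after the data were seen. It was tested on simulated data with 200 islands changed 4-fold. For the overexpression comparison it found 66.5% of them at 0.01 and 80% at 0.05 and called 2 of 18106 unchanged islands at 0.01, where the authors' formula called 801. For the day 5 comparison it found 82% at 0.01 and 90% at 0.05 and called 2 of 8081 unchanged islands, where the authors' formula called 154. As many islands were simulated as the merged lists hold. Their rates were drawn from the counts of the listed islands, pooled over both libraries, without the selection that island calling adds. Planted islands had 4 times that rate in the higher library, so most held more reads than listed islands do. How many islands the test would pass at the counts of the listed islands was simulated in 100 draws, with all listed islands changed by the same fold.

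To see what a shared wild type library gives with no change, 100 sets of 3 libraries were drawn at equal rates over 19523 islands merged from all 3 lists. The rates came only from the libraries in which an island was called, so simulated islands were shared more often than observed ones. A simulated island counted as called when it reached the lowest count that the library's list showed for its width.

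Named islands followed a rule written before the data were examined. For each comparison list these were the 10 islands with the largest authors' fold among those at FDR 0.01 or lower with at least 20 reads in the higher library, with ties in chromosome order. For each library they were the 5 islands with the most reads and the 5 widest. Alternatives were stricter read and FDR thresholds, other overlap definitions, merging within 5 kb, autosomes only, other scalings and placement within 1 Mb. Base composition, gene annotation and the gene lists fixed beforehand were left out. Gene models used here were of another build than mm9, and coordinates were not converted.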

Results

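SATB1 binding to chromatin was profiled by ChIP-seq in mouse embryonic stem (ES) cells of a line in which the transcription factor CDX2 can be switched on, which drives ES cells toward trophoblast. SATB1 is a nuclear protein that binds AT-rich DNA and organises chromatin, and ALKBH1 is a dioxygenase that can remove methyl groups from nucleic acids. The series held 4 samples: SATB1 ChIP from wild type ES cells, SATB1 ChIP after ALKBH1 overexpression, SATB1 ChIP from wild type cells at day 5 of differentiation, and an input sample, which was not analysed here. Each group had 1 library, so no difference between conditions could be set against a spread between replicates. Intervals given below are exact 95% intervals that cover counting error at most, taking reads, or islands where islands are counted, as independent. Read totals were 4921397 for wild type, 8482997 for overexpression and 5761224 for day 5, as recovered from the authors' normalised columns. Positions are on mouse build mm9, and what genes lie there was not analysed here.

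In all 3 libraries the regions with the most reads lay at the same places. The island with the most reads and the greatest width lay on chromosome 11. It spanned 3030801 to 3100200 with 3870 reads (interval 3749 to 3994) in wild type, 3027001 to 3101200 with 6769 reads (6609 to 6932) with overexpression, and 3030801 to 3100800 with 4343 reads (4215 to 4474) at day 5. In RPM, reads per 1000000 reads of the library, this was 786, 798 and 754, and the ratio to wild type was 1.01 with overexpression (0.975 to 1.06) and 0.959 at day 5 (0.918 to 1.00). The mitochondrial genome gave an island from 1 to 6600 with 754 RPM in wild type, 480 with overexpression and 461 at day 5. Its other island, from 10801 to 16200, held 759, 520 and 418 RPM. Overexpression over wild type was 0.636 (0.608 to 0.665) at the first and 0.685 (0.656 to 0.716) at the other, and day 5 over wild type was 0.611 (0.581 to 0.643) and 0.551 (0.523 to 0.580). A region on chromosome 9 starting at 3015201 held 1741 reads in wild type and 2093 with overexpression, each over 15.2 kb. The day 5 island there reached to 3032800 and held 2104 reads over 17.6 kb. All islands that overlap this day 5 span together held 2013 reads in wild type and 2417 with overexpression. Over that span wild type had 409 RPM, overexpression 285 and day 5 365. The ratio to wild type was 0.697 with overexpression (0.656 to 0.739) and 0.893 at day 5 (0.8395 to 0.9496). On chromosome Y, islands reaching to 2902600 held 1655 reads in wild type from 2874601, 3105 with overexpression from 2873001 and 1986 at day 5 from 2875001. In RPM these were 336, 366 and 345. The widest islands also included chromosome Y from 2849401 to 2872200 in wild type (1001 reads over 22.8 kb, 203 RPM), with counterparts from 2849601 to 2868400 with overexpression (1553 reads over 18.8 kb, 183 RPM) and from 2847601 to 2874000 at day 5 (1287 reads over 26.4 kb, 223 RPM). All overexpression islands that overlap the wild type span together held 1709 reads (201 RPM). Chromosome Y from 2779601 was among the 5 widest with overexpression (1362 reads over 17.8 kb, 161 RPM) and at day 5 (1059 reads over 18 kb, 184 RPM). Chromosome 8 from 19935201 to 19952400 held 434 reads (88.2 RPM) in wild type, and the overexpression island from 19936201 to 19951400 held 772 (91.0 RPM). Chromosome 4 from 145023201 to 145041000 held 237 reads at day 5. The 10 islands with the most reads took 15.9% of all island reads in wild type, 8.29% with overexpression and 23.1% at day 5. The input was not analysed here, so whether the reads at these regions, mitochondrial ones included, reflect SATB1 binding was not tested.

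The first comparison asked where SATB1 lay when ALKBH1 was overexpressed. More and narrower SATB1 islands were called with overexpression than in wild type: 14768 (14531 to 15008) against 6255 (6101 to 6412), a ratio of 2.36 (2.29 to 2.43). They covered 20.1 Mb against 10.8 Mb, with a median width of 1200 bp against 1600 bp, and held 4.04% of the library's reads (4.02 to 4.05) against 2.67% (2.65 to 2.68). Of the wild type islands, 2685 (42.9%) overlapped an overexpression island, where 100 random placements gave a mean of 129 and at most 162. The other islands were the majority in both lists: 12067 of the overexpression islands lay outside wild type islands. The overexpression library had 1.72 times the reads of the wild type library. With reads of overexpression islands thinned to the wild type depth, the ratio was 1.40, and among islands with at least the wild type median of 3.25 RPM it was reversed, at 0.585 (2006 against 3431 islands), as the plot of islands by minimum RPM shows. Median reads per island were 19 with overexpression and 16 in wild type, but 2.24 against 3.25 RPM. The lowest counts in the lists were 10 and 9 reads, so the deeper library admitted islands at lower RPM and its median RPM was lower in part by construction. At the 253 islands with identical coordinates in both lists, the median log2 ratio of RPM, overexpression over wild type, was -0.37, and 215 were lower with overexpression. An island had to reach a higher RPM to be called in wild type, so this ratio was also lowered in part by construction. Its value with no change was not computed.

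**Figure D1:**
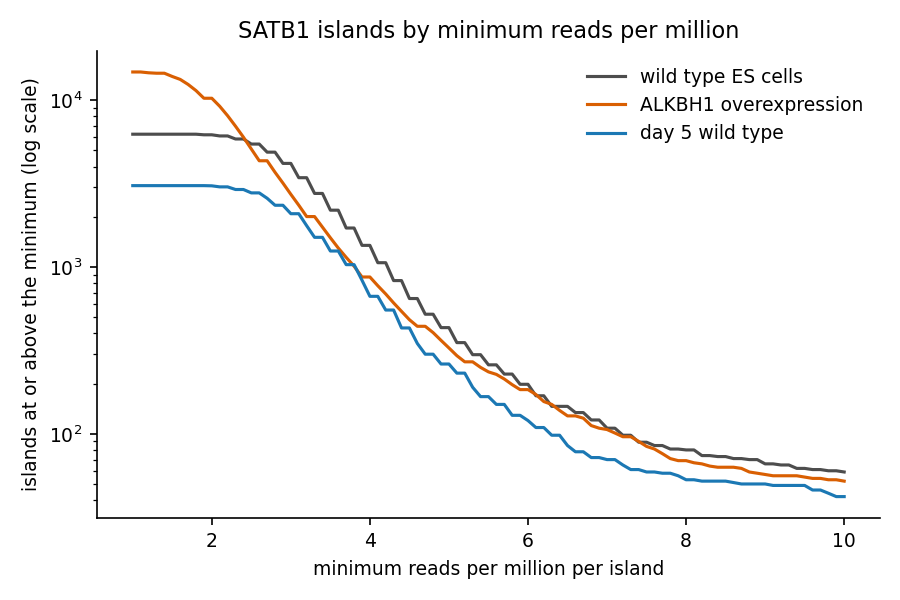
Number of SATB1 islands (log scale) at or above each minimum RPM per island, with 1 line per library. At a minimum of 2 RPM overexpression had 10275 islands against 6204 in wild type, and at 3 it had 2727 against 4180, while day 5 had 3067 and 2087.

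Among listed islands with at least 20 overexpression reads, those with the largest authors' fold in the authors' deposited table held 20 to 26 reads in the overexpression library and 0 or 1 in the wild type library. At chromosome 10 from 77496001 to 77497800, 24 reads (15.4 to 35.7) faced 0, 4.64-fold higher with overexpression when wild type is set to a floor of 3 counts, and with an exact lower limit of 3.49 for the ratio. Chromosome 8 from 85916401 to 85917400 had 21 reads against 0 (4.06-fold higher at that floor, exact lower limit 3.02), and chromosome 2 from 70966201 to 70967400 had 20 against 0 (3.87-fold higher at that floor, exact lower limit 2.86). Against 1 wild type read stood 26 reads at chromosome 12 from 50538401 to 50540800, an RPM ratio of 15.1 (2.48 to 618). The floor was not used at 1 read, so ratios at 1 read and at 0 reads cannot be ranked together. Both islands named on chromosome 13, from 16453801 to 16455400 and from 82619001 to 82621800, had 24 reads against 1, a ratio of 13.9 (2.27 to 573). Islands with 23 reads against 1, a ratio of 13.3 (2.17 to 550), lay on chromosome 5 from 123473401 to 123475000, chromosome 6 from 85112801 to 85114600, chromosome 9 from 76905601 to 76907200 and chromosome 11 from 74089401 to 74090600. These last 4 were the first by position of 6 islands tied in fold. In the authors' deposited table the fold, made with 1 read added to each count, ran from 6.96 at the last 4 to 14.5 at the chromosome 10 island, with an authors' FDR of 2.63e-17 there. None of these 10 islands overlapped a day 5 island. In the exact conditional binomial test on both counts, 0 of the 10 passed at 0.05, with adjusted exact p from 0.0901 to 0.108. The 10 were picked for the largest fold among 2711 eligible islands, so their ratios and limits lean high. The intervals do not allow for that choice.

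In all, the authors' deposited table listed 5270 islands as higher with overexpression, 28.8% of the 18306 merged islands, with a median authors' fold of 2.22. Of these, 14 overlapped a wild type island, so almost all were called in the deeper overexpression library and not in wild type. Median reads were 20 in the overexpression library and 4 in the wild type library, and the median RPM ratio, with 0 set to 3 counts, was 2.61. An exact conditional binomial test that takes counting error in both libraries into account passed 0 of the 5270 after adjustment, at 0.01 and at 0.05, with a smallest adjusted exact p of 0.0901. At these counts it would pass 45.6% at 0.05 if all listed islands differed 4-fold, and 1.58% (0.569% to 2.88% over the draws) if all differed 2-fold. Without adjustment 3079 islands had an exact one-sided p under 0.05. That test was chosen after the data were seen, and it compares these libraries, not the conditions. Scaled to the reads over the list itself, 1896 of the 5270 stayed higher with overexpression, a count that centring a one-sided list largely sets by construction.

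The next comparison followed SATB1 from wild type ES cells to day 5 of differentiation. Fewer and wider islands were called at day 5: 3075 (2967 to 3186) against 6255, a ratio of 0.492 (0.471 to 0.513), although the day 5 library had 1.17 times the reads. They covered 6.44 Mb with a median width of 1800 bp and held 1.52% of the library's reads (1.51 to 1.53). Of the wild type islands, 1046 (16.7%) overlapped a day 5 island, against a mean of 37.1 and a maximum of 52 in random placements. Of the day 5 islands, 1031 (33.5%) overlapped a wild type island and 1257 (40.9%) overlapped neither other list. Among islands with at least 16 reads, the wild type median, the ratio was 0.753, but 16 reads is a lower RPM in the deeper day 5 library. At an equal floor of 3.25 RPM the ratio was 0.516, and with island reads thinned to the wild type depth it was 0.470. At the 54 islands with identical coordinates the median log2 ratio of day 5 over wild type was -0.23, and 43 were lower at day 5.

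Among listed islands with at least 20 wild type reads, those with the largest authors' fold in the authors' deposited table held 20 to 23 reads in wild type and 2 to 4 at day 5. Islands with fewer reads had larger folds there, up to 19.9 at 16 reads against 0. Chromosome 4 from 138854201 to 138857000 had 22 reads against 2, a wild type over day 5 RPM ratio of 12.9 (3.17 to 113). Chromosome 3 from 33365201 to 33367400 had 21 against 2 (ratio 12.3, 3.00 to 108). With 3 day 5 reads, chromosome 2 from 169838801 to 169842800 had 23 wild type reads (ratio 8.97, 2.71 to 46.7), chromosome 8 from 77332401 to 77335800 had 22 (8.58, 2.58 to 44.8) and chromosome 9 from 98515401 to 98517000 had 21 (8.19, 2.45 to 42.9). A ratio of 7.80 (2.31 to 41.0), from 20 reads against 3, stood at chromosome 8 from 121889601 to 121891600, chromosome 11 from 74188201 to 74188800 and chromosome 12 from 80583601 to 80585800. Chromosome 8 from 112295201 to 112297200 and chromosome 13 from 113329401 to 113330600 had 23 reads against 4 (6.73, 2.3 to 26.8). In the authors' deposited table the fold at these 10 islands ran from 5.62 to 8.97. Of the 10, the islands on chromosomes 11 and 13 also overlapped an overexpression island. In the exact test on both counts, 4 of the 10 passed at 0.01 and all 10 at 0.05, with adjusted exact p from 0.00682 to 0.0127. These 10 were picked for the largest fold among 766 eligible islands, so their ratios and limits lean high too.

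The authors' deposited table listed 3341 islands as lower at day 5, 40.3% of the 8281 merged islands, with a median authors' fold of 2.51. Of these, 47 overlapped a day 5 island, so almost all were called in wild type and not at day 5. Median reads were 16 in wild type and 7 at day 5, and the median RPM ratio was 2.73. The exact test on both counts passed 20 at 0.01 and 890 at 0.05 of these 3341, and 2918 had an unadjusted exact one-sided p under 0.05. Both mitochondrial islands led the 20 by p, and whether their reads reflect SATB1 binding was not tested. Among the others, picked out here after their values were seen, were chromosome X from 166444801 to 166447000 with 46 reads against 17, and chromosome 15 from 3837801 to 3842000 with 29 against 6. Islands with 16 reads against 0 lay on chromosome 6 from 116231401 to 116234000 and on chromosome 17 from 88243001 to 88245000. Scaled to the reads over the list itself, 2539 of the 3341 stayed lower at day 5, a count that centring a one-sided list largely sets by construction.

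Of the 3325 wild type islands on the list, 32.2% (30.6 to 33.8) overlapped an overexpression island, against 55.1% (53.3 to 56.9) of the other wild type islands. Among islands with 20 reads or more the shares were 41.5% (37.9 to 45.1) and 69.9% (66.0 to 73.6), as in the plot of overlap by reads. In the other direction, 4.59% of the overexpression islands listed as higher overlapped a day 5 island, against 14.3% of the overexpression islands not listed. All of these groups were formed from wild type counts that both comparisons share, so part of each gap follows from the selection. Simulated libraries with no change gave 88.5% against 93.8% for the first pair of shares and 54.5% against 59.7% for the other. Those shares lie far above the observed ones, so they do not give the size of that part.

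**Figure D2:**
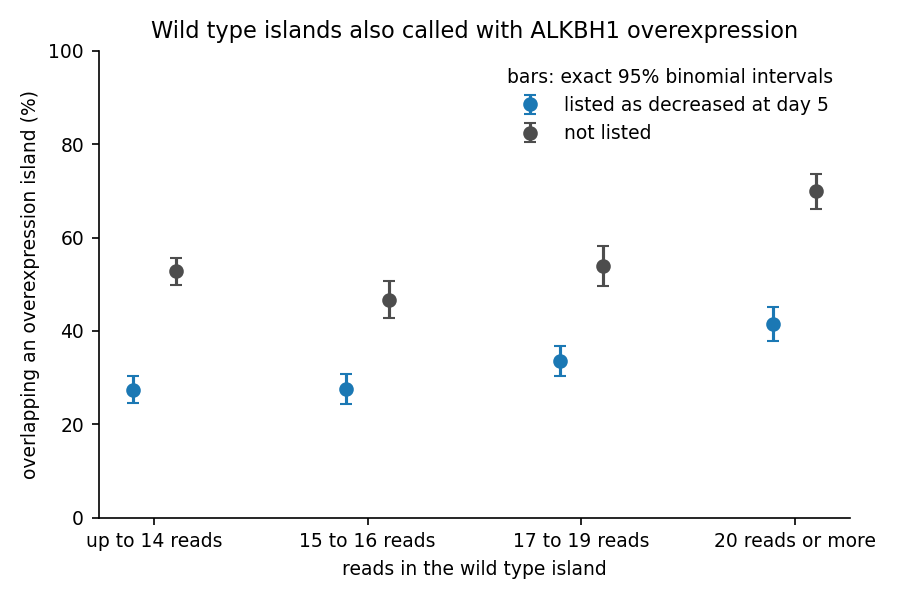
Percentage of wild type islands that overlap an ALKBH1 overexpression island, by reads in the island, for islands listed as decreased at day 5 and islands not listed. Points are shares and bars are exact 95% binomial intervals; with up to 14 reads the shares are 27.3% and 52.7%.

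The regions higher with overexpression and those lower at day 5 hardly met. Of the 5270 and 3341 islands, 5 overlapped, against a mean of 25.1 (12 to 41) in random placements. Random draws of 5270 of the merged overexpression and wild type islands met the list of islands lower at day 5 962 times on average (911 to 1020). Both lists rest on the same wild type library, low in one and high in the other, so a low overlap follows from the selection. Simulated libraries with no change gave lists of 780 and 180 islands on average, smaller than the observed ones, with 0.08 shared islands where independent lists of those sizes would share 7.21. Independent lists of the observed sizes would share 902. Overexpression and day 5 islands themselves overlapped at 1598 overexpression islands (10.8%), against a mean of 75 and a maximum of 99 in random placements. In all 3 lists at once, 784 wild type islands (12.5%) had a counterpart, and 3308 (52.9%) had none in either other list.

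Across the genome, chromosome 11 carried the most islands per Mb of any autosome in all 3 libraries, and the X chromosome carried few. Wild type cells had 5.57 islands per Mb on chromosome 11, against 1.51 on chromosome 14 and 3.04 on chromosome 17, the lowest and highest of the other autosomes. With overexpression the values were 11.4 on chromosome 11, 3.93 on chromosome 14 and 7.11 on chromosome 17. At day 5 they were 3.20 on chromosome 11, 0.687 on chromosome 14 and 1.55 on chromosome 8. Chromosome 11 held 10.8% of wild type islands (10.1 to 11.6), 9.39% with overexpression (8.93 to 9.87) and 12.7% at day 5 (11.5 to 13.9), on 4.61% of the sequence spanned. The X chromosome, 6.31% of the sequence spanned, held 22 wild type islands, 24 with overexpression and 10 at day 5. Those were 0.352% (0.221 to 0.532), 0.163% (0.104 to 0.242) and 0.325% (0.156 to 0.597) of the lists. Of the 22 wild type islands on X, 4 had counterparts in both other lists, among them the island from 139917401 to 139917800 with 99, 116 and 104 reads in wild type, overexpression and day 5. In RPM these were 20.1, 13.7 and 18.1.

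**Figure D3:**
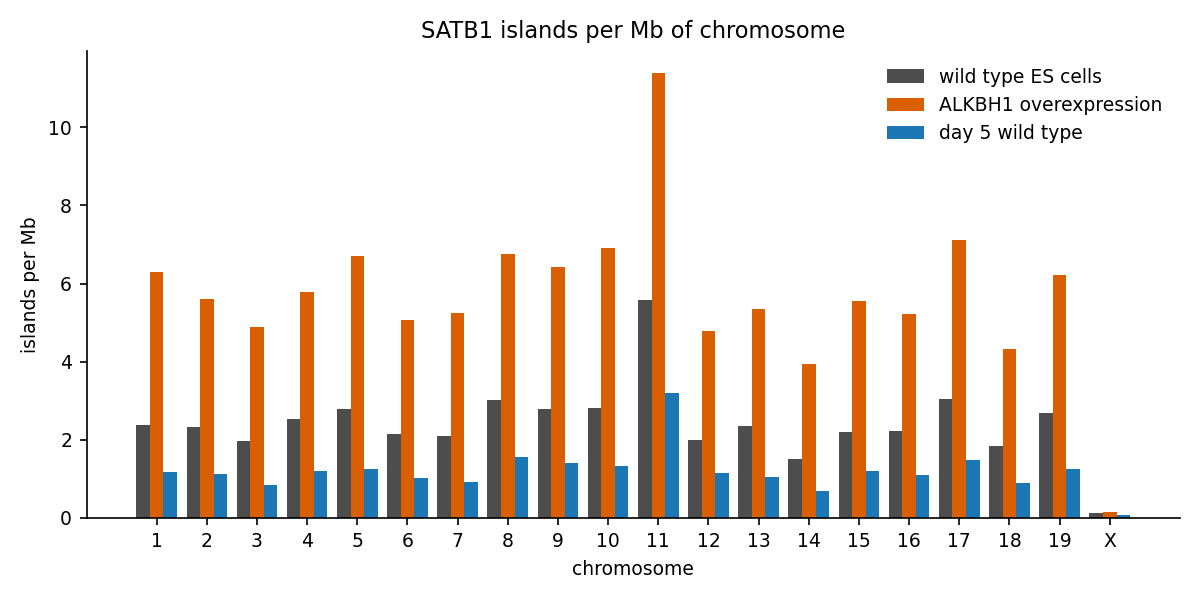
SATB1 islands per Mb of each chromosome from 1 to 19 and X, with 1 bar per library. Chromosome 11 stands highest in each library (5.57 in wild type, 11.4 with overexpression, 3.20 at day 5) and X lowest (0.132, 0.144 and 0.0601).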

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

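Tests at an RPM floor, after thinning, with RPM, with both counts or with identical islands were chosen after the results were seen; the others were planned. Of 60 alternatives, 17 stayed within the counting interval or within 1.5 times the count, as did all 40 for the 20 islands named by fold, whose counting intervals are very wide. Scaling to the list's reads still cut the named folds 2.54 times, to between 2.74 and 5.72, in the increased list and 2.15 times, to between 2.61 and 4.17, in the decreased list. The cause was not tested unless stated. The ratio of island numbers, overexpression over wild type, moved from 2.36 to 3.33 with at least 16 reads, 1.94 at a floor of 2.16 RPM per kb and 1.40 after thinning. It reversed to 0.585 at a floor of 3.25 RPM. Day 5 over wild type gave 0.753, 0.392, 0.470 and 0.516 in that order, from 0.492. Median reads per island, overexpression over wild type, went from 1.19 to 1.51 per kb, and reversed to 0.689 in RPM and 0.874 in RPM per kb, in part by construction, since the lowest counts were about the same. Day 5 went from 1.19 to 1.01 per kb and 1.01 in RPM and reversed to 0.861 in RPM per kb.

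Overlap over random placement stayed far above 1. For wild type with overexpression it was 20.8, and 37.7 with 50% of the first island, 51.9 with 50% of both, 10.0 with 1 kb added and 14.6 with placement within 1 Mb. For wild type with day 5 it was 28.2, then 44.1, 60.2, 15.1 and 19.3, and 25.7 in islands at or above the median reads. For overexpression with day 5 it was 21.3, then 32.1, 50.0, 11 and 15.7. The stricter list (fold 2, FDR 1e-05) held 1522 of the 5270 increased and 667 of the 3341 decreased islands. Scaling to the list's reads left 1896 increased islands higher, which centring a one-sided list brings by construction. The exact test on both counts passed 0 increased islands at 0.01 and 0 at 0.05, and 20 and 890 decreased islands. The overlap of the lists was 5, then 3 with 50% of both and 0 under the stricter list. Chromosome 11 over the other autosomes was 2.39 in wild type, 2.04 with overexpression and 2.79 at day 5. It was 2.65, 2.29 and 3.48 by covered bases, and 2.61, 2.31 and 3.12 in islands at or above the median reads. The X share with overexpression was 0.243% by covered bases. Base composition, gene annotation and gene lists were not run. No paired analysis was possible because each group had 1 library.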

Other observations

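The tests in this part were added after the data were seen. For the overlaps with moved islands, the bounds were written before their values were seen. SATB1 islands lay closer together than random placement gives. On autosomes the median distance between neighbouring island starts was 167 kb in wild type, against a mean of 255 kb in 100 random placements (243 to 264). With overexpression it was 79 kb against 109 kb (107 to 112), and at day 5 it was 375 kb against 506 kb (477 to 529). The lower library of each comparison still held reads above an even spread. At the autosomal increased islands wild type had a median of 3.21 reads per kb, 1.72 times an even spread of its reads over 2640 Mb. At the decreased islands day 5 had 4.15, 1.90 times an even spread.

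The 5270 islands listed as higher with overexpression are the first pattern. Chance-high counts in the overexpression library alone stay open. These islands overlapped day 5 islands 7.33 times as often as islands moved at random within 1 Mb, above the bound set beforehand. All overexpression islands gave 15.7 by the same measure. Moved islands do not keep to places where all libraries hold more reads, so this cannot exclude chance-high counts at such places. Counting error of the wild type library stays open: 0 of them passed an exact test on both counts at 0.05. That is far below the 45.6% that a 4-fold change of all of them would give. A 2-fold change of all would give 1.58%, with 0.569% to 2.88% over the draws, also above 0. Smaller changes, or changes of part of the list, were not simulated, so the test cannot decide between counting error and those. In unchanged islands simulated at rates of the listed islands, without the selection of island calling, the authors' formula called 4.42%. Here 28.8% were listed, so counting error could account for part of the list. A change in SATB1 binding with ALKBH1 overexpression also stays open, untested for lack of replicates.

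The 3341 islands listed as lower at day 5 are the next pattern. Counting error of the day 5 library alone, with wild type counts taken as true, is argued against as the whole cause. Of the listed islands, 890 (26.6%) passed the exact test on both counts at 0.05, against 11.2% in simulations where all differed 2-fold. The authors' formula called 1.91% of simulated unchanged islands where 40.3% were listed. Chance-high counts in the wild type library alone stay open. The listed islands overlapped overexpression islands 10.8 times as often as moved islands, above the bound set beforehand, where all wild type islands gave 14.6. As for the first pattern, moved islands cannot exclude chance-high counts at places where all libraries hold more reads. Counting error of both libraries together, high in wild type and low at day 5, stays open for part or all of the list. The exact test and the simulated unchanged islands leave out that islands were called for high counts, so neither can exclude it. Loss of SATB1 binding during differentiation stays open, and 1 library per day cannot separate it from a less efficient precipitation.

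Chromosome 11 had 2.39 times the islands per Mb of the other autosomes in wild type, and X few in each library. A few dense clusters are argued against, since 100% of the 12 full 10 Mb bins of chromosome 11 lay above the median bin of the other autosomes in wild type. With overexpression it was 100% too, and at day 5 it was 11 of 12 bins (91.7%). A single copy of X, on which the labels say nothing, may account for part of its low density: autosomal reads thinned to 1 of 2 left 12.4% of wild type islands, 13.2% with overexpression and 6.27% at day 5 at or above the lowest count for their width, against X densities of 5.25%, 2.42% and 4.85% of the autosomal ones. With exactly 1 of 2 reads the shares were 4.79%, 6.26% and 2.91%, so X lay between both estimates in wild type and at day 5 and below both with overexpression. Islands on Y were called in each library (7 in wild type, 8 with overexpression, 5 at day 5), but copies of X were not measured. An extra copy of chromosome 11 cannot be told apart from denser binding: thinning its reads to 2 of 3 brought the ratio to 1.09, but wild type reads per kb at its increased islands were 1.03 times those elsewhere, at islands selected for few wild type reads.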
